A study of Arabidopsis thaliana with 4 samples.

How the data were processed

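Total RNA from axillary buds before decapitation (2 arrays) and from axillary shoots 24 h after it (2 arrays) was extracted with a column kit, labelled with biotin by in vitro transcription from the 3' end and hybridized to ATH1 arrays, per the labels' protocols. Plants grew in soil mix under continuous light. The deposited values are probe set intensities on a linear scale, made with MAS5 in GCOS per the submitters' processing notes; versions and the treatment of the scanner images are not given in the sources used here. In the deposited intensity table the mean of each array without its lowest and highest 2% of probe sets was 100, so each array had been scaled to a common target, and no value was at or below 0. Because of this scaling a change in total RNA per cell cannot be seen. MAS5 subtracts mismatch signals, which makes dim probe sets noisy, and detection calls were not used here. Every column matched 1 sample.

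Replicate numbers come from the labels, which do not say whether the 2 arrays of a group came from separate plants; p-values therefore measure only the spread between these samples, which may be technical. The 64 control probe sets were left out of the tests. A probe set was tested when its mean log2 signal over the 4 arrays was in the upper 60% of the 22746 others, which left 13648 with a geometric mean signal of at least 23.1. Log2 signals were compared between shoots and buds with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), and p-values were adjusted after Benjamini and Hochberg, with a threshold of 0.05. No further scaling between arrays and no pseudocount were applied. Fold changes are ratios of geometric means, and means ± SD are of linear signals. All 4 arrays entered the fit.

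Genes were named through a platform annotation dated before the current gene models and a table of the TAIR10.1 gene set. Of the 22746 probe sets, 13513 had 1 gene, 503 had several and 8730 were not listed; 13436 matched 1 of 13286 loci. Probe sets with several genes or without a listing were tested and counted but not named, and 6292 of the 13648 tested probe sets are unnamed here. The branching and dormancy genes BRC1, BRC2, DRM1 and DRM2 and the cyclin gene CYCB1;1, which were to be named wherever measured, are not analysed here.

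Gene lists were tested with camera (preset correlation between genes of 0.01), using for each locus its brightest probe set, when at least 5 loci were tested. Camera with an estimated correlation and fry were run beside it, and p-values were adjusted over the 20 lists tested. Camera compares a list with the other genes, whereas fry tests it against no change. Before the data were examined, 25 lists were written, on dormancy, hormones, cell cycle, ribosomes, starvation, stress, light harvesting, cell walls and other themes; the ribosomal, cell cycle, starvation and dormancy lists were written with knowledge that the experiment had been published on. The annotation left 10 of these lists without a tested locus, 14 with 1 to 4 and 1 with 5 or more. A further 20 lists, of cellular machineries and gene families, were written after the coverage of the annotation was known and before any fold change was computed. Of these, 19 had at least 5 tested loci. Those on ribosomes, cell cycle and starvation came after the same knowledge, so their direction is not independent evidence. The results of 1 of the 20 lists tested, and of single loci related to it, are not reported here. None of the 8 lists that passed did so with an estimated correlation, and 1 passed with fry. Both of these tests rest on the few residual degrees of freedom that 4 arrays in 2 groups leave, which makes a pass hard to reach. With camera the adjusted p was 0.553 alike at estimated correlations of −0.07 (starvation) and 0.902 (first ribosome biogenesis list). A miss therefore does not show that correlation between genes accounts for a shift.

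Genes were named by a rule set before the data were examined: the 12 largest increases and 12 largest decreases with 1 locus that passed the threshold and whose groups did not overlap, and in each list up to 4 loci, those with the 2 smallest p-values and the 2 largest changes. Names outside this rule, which illustrate short lists or loci of low count, were chosen after their values were seen. A test of promoter motifs in called genes was planned and not run, as no genome sequence was used here.

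Both tests were tested on simulated data with the means and spread of these arrays. For shoots against buds, over 20 simulated sets of 13648 probe sets with 200 changed, 9.85% of 2-fold and 86.3% of 4-fold changes were recovered, and 5.27% of the calls were false. Far more probe sets, 3023, were called in the data, and the adjusted threshold depends on that share. The simulated recovery therefore does not give the recovery in this comparison. A list of 20 loci shifted by 0.5 on the log2 scale was found in 20 of 20 sets, with 1 false call among 380 unshifted lists; the simulated genes were uncorrelated. Alternatives covered the scaling between arrays, a pseudocount of 6.41, the filter, the variance trend, the replicate number as a block, each array left out, a plain 2-fold criterion and the choice of probe set and list test. Scaling to 9 spike probe sets, leaving out bright probe sets and removing the trend on gene length were added after the data were seen.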

Results

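Gene expression was measured in axillary buds and young axillary shoots of Arabidopsis thaliana Col-0, a standard laboratory accession, on ATH1 GeneChips, short-oligonucleotide arrays for the Arabidopsis genome. Decapitation is the removal of the main shoot apex, which in many plants releases the axillary buds below it to grow. Buds taken before decapitation and shoots taken 24 h after it were each represented by 2 arrays, called bud arrays and shoot arrays here. Each array held 22810 probe sets, of which 64 were controls. The median signal was 46.4 and 43.6 on the bud arrays and 40.9 and 40.6 on the shoot arrays, and the highest signal lay between 1144 and 1559. Over the 13648 probe sets tested, log2 signals correlated across genes at r = 0.952 between the bud arrays and 0.958 between the shoot arrays. Between a bud array and a shoot array r lay between 0.808 and 0.895; genes are not independent replicates. The ratio of the 3' to the 5' actin control probe set was 1.66 and 1.38 on the bud arrays and 0.990 and 1.14 on the shoot arrays, and that of an older actin set 5.81 and 6.67 against 2.13 and 3.19. The same ratio for GAPDH (1.198 and 1.081 against 1.142 and 0.938) and ubiquitin (0.704 and 0.963 against 0.718 and 0.887) did not separate the groups, and that of an older GAPDH set was 1.51 and 0.812 against 0.714 and 0.601. The number of arrays limits the precision of every value, and an exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333.

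The comparison of shoots with buds asked which transcripts differ between buds before decapitation and axillary shoots 24 h after it. No buds of intact plants were sampled at the later time. Decapitation, wounding, 24 h of further age, harvest time and tissue make-up therefore cannot be told apart. Higher or lower after decapitation names the groups here and not a cause. Among probe sets with a named gene, AT4G11190, a dirigent-like gene, had the largest fitted increase, from a signal of 7.36 ± 1.27 to 88.2 ± 38.6 (mean ± SD, n = 2 in each group), or 11.5-fold (limma log2 fold change 3.52, adjusted p = 0.00211). Its bud signals lay below 23.1, the lowest mean signal tested, and were not shown to be above background, so this fold and rank are uncertain: with a pseudocount of 6.41 it was 6.59-fold higher and AT4G17470 8.44-fold higher. AT3G10040 (HRA1), a transcription factor gene of the hypoxia response, rose 6.70-fold, and UF3GT (UGT79B1), which encodes a glycosyltransferase of anthocyanin synthesis, rose 6.62-fold from 64.0 ± 18.7 to 416 ± 59.0. HIS1-3, which encodes a linker histone variant known from drought responses, had the largest fitted decrease among named genes, from 365 ± 257 to 10.7 ± 0.527 (29.7-fold lower, log2 fold change −4.89, adjusted p = 0.00140). Its shoot signals also lay below 23.1, and the fold was 18.98 with the pseudocount, 17.2 without bud array 1 and 51.3 without bud array 2. COR27, a cold-regulated gene, was 7.63-fold lower, and RING1, which encodes a ubiquitin ligase, 6.43-fold lower.

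The other genes of the 12 largest named increases were AT4G17470, AT5G45700, AT1G06100, JAL23, AT2G42110, AT1G63100, AT4G15830, AT1G73620 and AT3G15550, with log2 fold changes from 2.57 for AT3G15550 to 3.48 for AT4G17470. The other genes of the 12 largest named decreases were AT1G22890, AT3G62550, AT2G15830, AT1G78460, AT1G32700, AT1G76590, AT1G01240, AT4G17245 and AT1G21680, with log2 fold changes from −3.62 for AT1G22890 to −2.73 for AT1G21680. By the naming rule, all 24 genes passed the test and had both shoot arrays on the same side of both bud arrays. With shoot array 1 left out, AT2G42110 (adjusted p = 0.0959) and AT3G15550 (adjusted p = 0.0773) missed the threshold, and the other 22 passed with any 1 array left out. Log2 fold changes of AT5G45700, JAL23, AT2G42110, AT1G63100 and AT3G15550 were 1.62 to 2.07 without bud array 1 and 3.25 to 3.73 without bud array 2, and that of AT1G01240 was −2.13 without shoot array 1 and −3.53 without shoot array 2. Both signals of 1 group lay below 23.1 also for AT3G10040, AT2G15830, AT1G78460 and AT1G76590 here and for AT3G44050, HTR12, LTI30 and UGT72E1 below, so the sizes of their folds are uncertain.

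**Figure D1:**
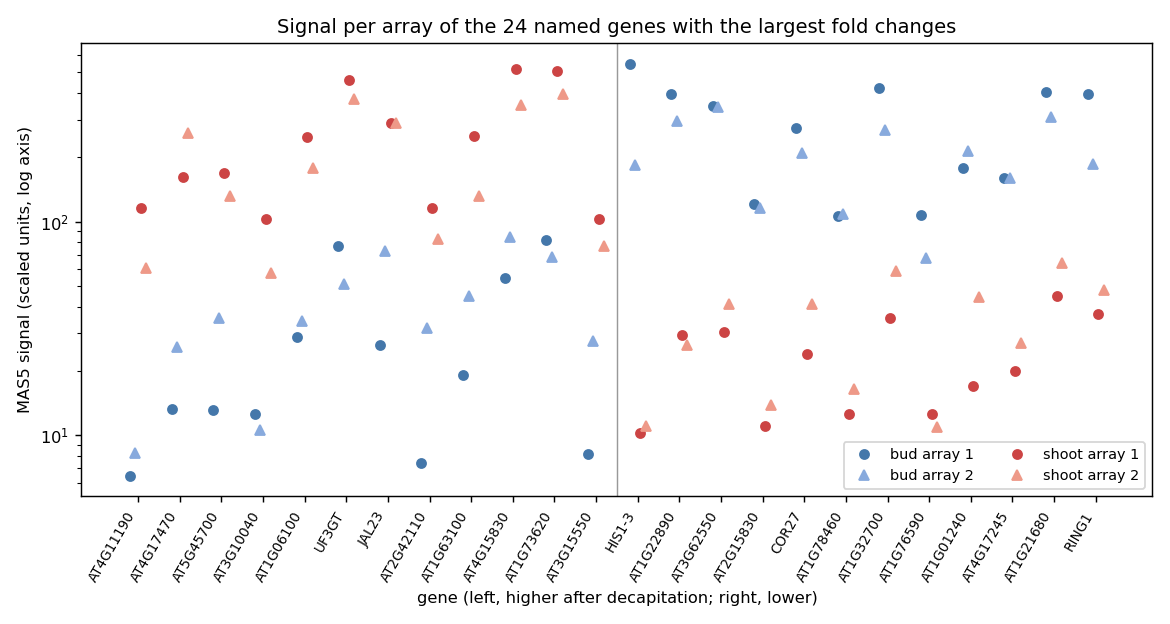
Signal on each of the 4 arrays (vertical axis, MAS5 signal in scaled units, log axis) for the 12 named genes with the largest fitted increases and the 12 with the largest fitted decreases (horizontal axis). Each point is 1 array. For HIS1-3 the bud arrays averaged 365 and the shoot arrays 10.7. The shoot points of every gene drawn lie on 1 side of the bud points because the naming rule required it.

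Of the 13648 probe sets tested, 1388 were higher and 1635 lower after decapitation at an adjusted p of 0.05 or less (limma with Benjamini-Hochberg adjustment), or 22.2% together. A change of at least 2-fold was found for 803 of the higher and 1032 of the lower probe sets. A single named gene was matched to 701 of the higher and 865 of the lower probe sets. The groups did not overlap at 65.2% of all tested probe sets, where chance gives 33.3%. Of the calls, 45.9% were higher; with the medians of the arrays set equal this share was 61.1%, and the median log2 fold change of all tested probe sets moved from −0.06 to 0.08. Leaving out shoot array 1 gave 230 probe sets higher and 432 lower, and without bud array 1 the number lower was 944.

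Most tested genes of mitosis rose in the shoots. Of 18 tested loci in a list of kinesins, condensin subunits, kinetochore and spindle checkpoint genes, 14 rose, 0 fell and 4 did not pass, with a median fold change of 2.99 (log2 1.58); adjusted over the list alone 15 rose and 1 fell, the kinesin gene AT3G45850 (log2 fold change −0.59, adjusted p = 0.0740 over all probe sets), named after its value was seen, which also fell with a replicate block. Kinesin genes were among the largest: AT3G44050 rose 4.89-fold from 13.3 ± 2.42 to 68.3 ± 33.0, AT3G20150 4.42-fold and AT2G28620 4.08-fold (n = 2 in each group). The Aurora kinase genes AUR2 (5.33-fold, 41.5 ± 23.9 to 209 ± 77.4) and AUR1 (log2 fold change 1.85, 71.7 ± 33.2 to 247 ± 56.3), whose products act in chromosome segregation and division plane formation, rose as well, while AUR3 had a log2 fold change of 0.54 (adjusted p = 0.183). Camera placed the 18 loci above other genes (adjusted p = 2.11e-08, or adjusted p = 0.553 with an estimated correlation). The list was written after the publication on the experiment was known, so its direction is not independent evidence. Without shoot array 1, 1 of the 18 loci passed, at a median log2 fold change of 1.27, and AUR2 (adjusted p = 0.0515) and AUR1 (adjusted p = 0.0585) missed the threshold. AUR2 was 3.46-fold higher without bud array 1 and 8.21-fold without bud array 2, and the actin ratios given above moved with the mitotic genes too.

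Several DNA replication and histone genes rose as well. PRL, which encodes the MCM7 subunit of the replicative helicase, rose 3.42-fold from 84.6 ± 9.57 to 293 ± 72.8 (adjusted p = 0.00385, n = 2 in each group). Of 5 further replication loci, 3 rose: ICU2, the catalytic subunit of DNA polymerase alpha (3.19-fold), POLA3, a primase subunit (2.16-fold), and POLD3, a subunit of DNA polymerase delta, with a log2 fold change of 0.97; PSF2 (0.31) and AT5G26680 (0.48) did not pass. Of 38 listed core histone loci 7 had a named probe set, all of histone H2B genes; of the 6 tested 4 rose, with HTB2 3.28-fold and AT2G37470 3.41-fold higher, while HTB4 (log2 fold change 0.69) and AT2G28720 (−0.46) did not pass. HTR12, the centromeric histone H3, which is also counted among the mitotic loci above, rose 2.43-fold. Camera gave an adjusted p of 0.00775 for the replication loci and 0.00500 for the H2B loci, and an adjusted p = 0.553 for both with an estimated correlation. As with the mitotic list, knowledge of the publication came before the replication list, so its direction is not independent evidence. When shoot array 1 was left out, 0 of the 5 replication loci passed, with ICU2 at an adjusted p of 0.0603, and HTR12 missed the threshold without that array (adjusted p = 0.219) or bud array 1 (adjusted p = 0.0798), or with no filter (adjusted p = 0.0558). The 3' to 5' actin ratio moved with these groups, from 1.66 and 1.38 on the bud arrays to 0.990 and 1.14 on the shoot arrays.

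Many tested genes of ribosome assembly rose in the shoots. In the list fixed before the data were examined, 6 of 9 tested loci rose and 0 fell, or 7 adjusted over the list alone, with a median fold change of 2.00. AT3G05060, which encodes a nucleolar NOP58-like protein, rose 2.46-fold from 190 ± 16.4 to 475 ± 122, and AT1G52930, related to the yeast assembly factor BRX1, rose 2.39-fold (n = 2 in each group). In a further list 17 of 29 loci rose and 0 fell, with AT5G11240 2.75-fold, the nucleolar gene YAO 2.41-fold and AT3G21540 3.15-fold higher. The first list was written with knowledge that the experiment had been published on, and the further list came later on the same theme. The direction of neither is independent evidence. Camera gave an adjusted p of 7.62e-05 for the first and 6.26e-10 for the further list, and 0.553 is the adjusted p of both with an estimated correlation. Without shoot array 1, 0 of the 9 and 0 of the 29 loci passed, at median log2 fold changes of 0.82 and 0.71, and without bud array 2, 9 of the 29 passed, with AT3G21540 at 0.89 (adjusted p = 0.106; 2.42 without bud array 1), which also missed the threshold with no filter (adjusted p = 0.0820) or no variance trend (adjusted p = 0.0523). The actin ratio, 1.66 and 1.38 before against 0.990 and 1.14 after decapitation, moved with these lists too.

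Genes of cytosolic ribosomal proteins were higher on balance. Of 117 tested loci, 37 rose, 3 fell and 77 did not pass, with a median fold change of 1.25. AT1G23410 rose 4.48-fold from 24.2 ± 1.98 to 109 ± 8.74, and AT1G07070 rose 3.51-fold from 113 ± 9.54 to 396 ± 59.2 (n = 2 in each group). The 3 that fell were AT3G09200 (log2 fold change −1.52), AT5G20290 (−1.31) and AT2G34480 (−1.16), named after their values were seen; the bud signals of AT3G09200 and AT2G34480 were 1000 or more, where the signal may be compressed. Grouped by their bud signal, 14 of 16 loci at 200 to 400 rose, and of 32 at 1000 or more 0 rose and 2 fell (median log2 fold changes 1.07 and −0.28). Grouped by their shoot signal, 6 of 9 at 200 to 400 rose and 2 fell, and 6 of 30 at 1000 or more rose (0.88 and 0.25); the grouping itself depends on the change, so no trend with signal is read from this. Camera gave an adjusted p of 3.33e-06 for the 117 loci, against an adjusted p = 0.553 with an estimated correlation, beside the same shift of the actin ratio as above. This list too was written after the publication was known, so its direction is not independent evidence. Many of these genes have near-identical copies, so the values of single members are uncertain; without shoot array 1, 14 of the 117 rose and 0 fell, and without shoot array 2, 10 fell. The number that fell was 0 with no filter, 5 with quantile normalization, 8 with spike scaling and 14 with a replicate block.

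**Figure D2:**
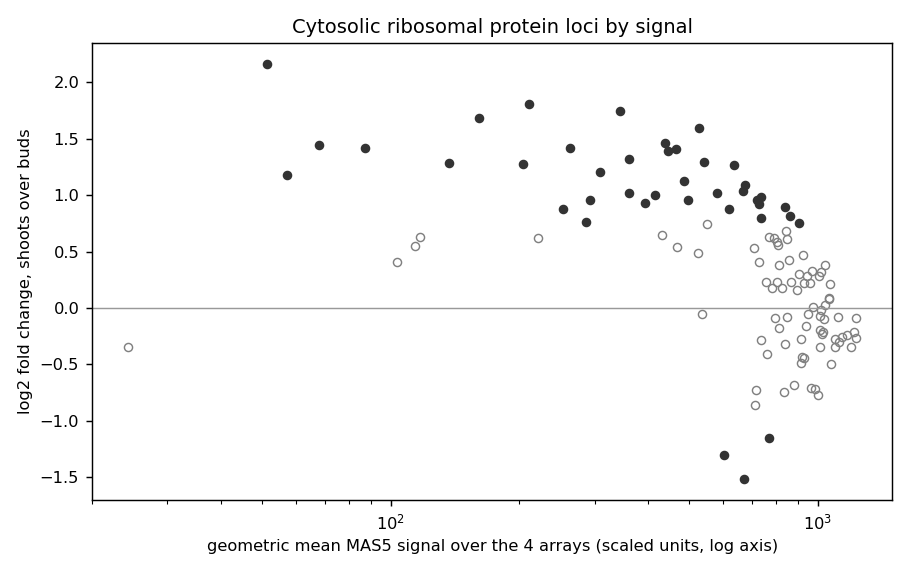
Log2 fold change of the 117 cytosolic ribosomal protein loci (vertical axis) against their geometric mean MAS5 signal over the 4 arrays (horizontal axis, scaled units, log axis). Each point is 1 locus, filled where the adjusted p was 0.05 or less; the 26 loci at a signal of 1000 or more have a median of −0.20, and the 12 loci between 200 and 400 a median of 1.12. With the highest signals of these arrays, a mean of 1000 leaves room only for log2 fold changes from −1.05 to 0.68.

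Lists of other genes of protein synthesis and turnover were tested as well. Of 6 proteasome loci, 3 rose and 0 fell, with AT5G23540 1.82-fold and AT5G45620 1.66-fold higher (camera adjusted p = 0.00607; adjusted p = 0.553 with an estimated correlation). Without bud array 1 or shoot array 1, 0 of these 6 loci passed, and without shoot array 2, 1 did; 1 of 6 passed with quantile normalization, with no filter or with no variance trend, in each of which AT5G45620 missed the threshold (adjusted p = 0.0574, 0.0753 and 0.0650). The actin ratio (1.66 and 1.38 in buds, 0.990 and 1.14 in shoots) moved with the proteasome loci as well. Of 13 translation factor loci, 5 rose and 2 fell, with AT5G12110 3.15-fold and AT2G40290 1.94-fold higher, and the list did not pass (adjusted p = 0.0513). Without bud array 1 or shoot array 1, 1 translation factor locus rose and 0 fell, with AT2G40290 at adjusted p values of 0.0699 and 0.119, and without bud array 2 or shoot array 2, 3 rose and 1 fell. Of 10 plastid ribosomal protein loci, AT5G24490 fell, with a fitted fold of 2.46, from 1222 ± 232 in buds, where signals of 1000 or more may be compressed, to 500.1 ± 120 (n = 2 in each group), which missed the threshold without shoot array 1 (adjusted p = 0.0862), and the other 9 did not pass; the list had an adjusted p of 0.756. A gene with the synonym RPS13, AT1G77750, was 1.72-fold higher, and missed the threshold without bud array 1, shoot array 1 or shoot array 2 (adjusted p = 0.0897, 0.141 and 0.0717).

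Some genes linked to energy starvation and to drought fell in the shoots. Of 8 loci in a list of starvation and amino acid catabolism genes, 4 fell and 0 rose, with a median log2 fold change of −0.97. AKINBETA1, which encodes a regulatory subunit of the energy-sensing kinase SnRK1, fell 3.49-fold from 319 ± 18 to 91.4 ± 2.69, AT5G19120 fell 2.68-fold and AT1G66180 2.11-fold (n = 2 in each group). Of 25 loci in the sugar starvation list, 4 had a named probe set. Of these 4, all tested, 2 fell, or 2 adjusted over the list alone: AT3G15450 by 4.66-fold from 893 ± 167 to 190 ± 1.1, and MCCA, a gene of leucine breakdown, by 1.70-fold. Only 4 of 38 loci in the abscisic acid and drought list had a named probe set. These were LTI30 (5.19-fold), COR47 (2.78-fold), COR15A and COR15B, which are also cold-regulated genes. All 4 fell, and 4 fell adjusted over the list alone. The rest of both lists was not seen here. Camera gave an adjusted p of 0.0162 for the 8 starvation loci (adjusted p = 0.553 with an estimated correlation), fry 0.0411, and 0.0860 for 9 late embryogenesis abundant loci, of which the same 4 fell.

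The starvation and drought genes depended on single arrays as well. Without shoot array 1, 2 of the 8 starvation loci passed, while AT1G66180 (adjusted p = 0.0528), AT5G19120 (adjusted p = 0.103), COR47 (adjusted p = 0.0655), COR15A (adjusted p = 0.125) and COR15B (adjusted p = 0.231) did not. COR15B also missed the threshold without bud array 1 (adjusted p = 0.0670) or bud array 2 (adjusted p = 0.0757). MCCA missed the threshold with any 1 array left out, at adjusted p values from 0.0715 to 0.231, and with other scalings or no filter (0.0586 to 0.135). Both starvation lists were written knowing of the published study, which makes neither independent evidence of direction. The actin ratios of 1.66 and 1.38 against 0.990 and 1.14 moved with the starvation and drought genes as well.

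Single genes of hormone, clock and cell wall lists changed in both directions. ARR15, a cytokinin-induced response regulator gene, rose 4.31-fold from 24.8 ± 10.3 to 102 ± 0.0644, whereas RR16 had a log2 fold change of −0.62 (adjusted p = 0.174). Of the auxin-conjugating enzyme genes, WES1 (GH3.5) fell 4.32-fold from 324 ± 44.0 to 75.5 ± 15.3 and GH3.3 rose 2.37-fold (n = 2 in each group); HAT2 had a log2 fold change of −0.26 (adjusted p = 0.671). GI, a clock gene, fell 2.50-fold. YAB3, a gene of organ polarity, rose 1.74-fold. LHCB4.3, a light-harvesting protein gene, fell by 0.96 on the log2 scale, while LHCB4.1 (0.57) and LHCB4.2 (−0.03) did not pass. STZ, an early stress gene, had a log2 fold change of 0.47 (adjusted p = 0.474), which was −0.28 without shoot array 1 and 1.22 without shoot array 2.

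Over the 14 lists with 1 to 4 tested loci, which had no list test, 10 of 30 loci rose and 10 fell, against 12 and 10 adjusted over the list alone. Of the 22 loci that the naming rule picked from these lists, 18 passed, 7 without shoot array 1 and 12 without bud array 1. Among those that missed the threshold without shoot array 1 were GH3.3 (adjusted p = 0.166), GI (adjusted p = 0.0550), YAB3 (adjusted p = 0.220) and LHCB4.3 (adjusted p = 0.192). GH3.3, YAB3 and LHCB4.3 also missed it without bud array 1, at adjusted p values of 0.0598, 0.0717 and 0.117, and YAB3 without bud array 2 (0.0706); YAB3 (0.0512) and LHCB4.3 (0.0528) missed it with no filter as well. The actin ratios given above moved with the groups for these genes as well.

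Of 9 loci of the expansin and xyloglucan transglucosylase families, which loosen cell walls, 4 rose and 1 fell: EXPA15 rose 2.81-fold from 128 ± 58.4 to 342 ± 42.6, EXPB3 rose 2.25-fold and EXPA8 fell 4.94-fold from 140 ± 6.51 to 32.3 ± 21.9 (n = 2 in each group). The list did not pass (camera adjusted p = 0.0853), 1 of its loci rose without shoot array 1 and 2 rose without bud array 1 or shoot array 2. EXPA15 (adjusted p = 0.0822) missed the threshold without shoot array 1 and EXPB3 (adjusted p = 0.0540) without shoot array 2; EXPA8 was 2.93-fold lower without shoot array 1 and 8.34-fold without shoot array 2. Of 7 tubulin loci TUB7 rose 2.33-fold, and missed the threshold without shoot array 1 (adjusted p = 0.0822); TUA1 had a log2 fold change of −0.53 (adjusted p = 0.0966).

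The other lists described here were gene families and did not pass. The actin ratios given above moved with the groups for their loci and for the cell wall and tubulin loci as well. Of 20 UDP-glycosyltransferase loci, 2 rose and 5 fell, with UGT72E1 5.07-fold and UGT71C5 2.72-fold lower (list adjusted p = 0.434); without shoot array 1, 1 rose and 1 fell, without bud array 1, 3 fell, and with a replicate block 8 fell. Of 8 SWEET sugar transporter loci, SWEET11 (3.17-fold) and SWEET13 (2.37-fold) fell and SWEET17 rose 1.78-fold (list adjusted p = 0.563). Among 13 serine carboxypeptidase-like, 7 beta-glucosidase and 5 tetraspanin loci, SCPL34 (−0.94), BGLU33 (−1.85) and TET3 (−1.19 on the log2 scale) fell and 0 rose, with list adjusted p values of 0.702, 0.434 and 0.841; SCPL49 (−0.56), BGLU15 (1.13) and TET7 (0.29) did not pass, although 2 beta-glucosidase loci rose without bud array 2, with equal medians or with a replicate block. Of 14 trichome birefringence-like loci TBL26 rose 2.42-fold, while TBL37 (−0.67) and TBL32 (−0.76) did not pass (list adjusted p = 0.970). The loci UGT71C5 (adjusted p = 0.0514), SWEET11 (0.106), SWEET13 (0.232), SWEET17 (0.0909), SCPL34 (0.238), BGLU33 (0.0676, at a log2 fold change of −1.04; −2.65 without shoot array 2) and TET3 (0.145) missed the threshold without shoot array 1. SWEET11, SWEET13, SWEET17 and SCPL34 also missed it without bud array 1 (0.0594, 0.182, 0.114 and 0.136), SCPL34 without bud array 2 (0.0551), and SWEET17 (0.124) and TBL26 (0.0735) without shoot array 2. SWEET13 and SCPL34 missed it with quantile normalization (0.0601 and 0.0578) or no filter (0.0815 and 0.0694) as well, and SCPL34 with equal medians (0.0588) or spike scaling (0.0581).

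**Figure D3:**
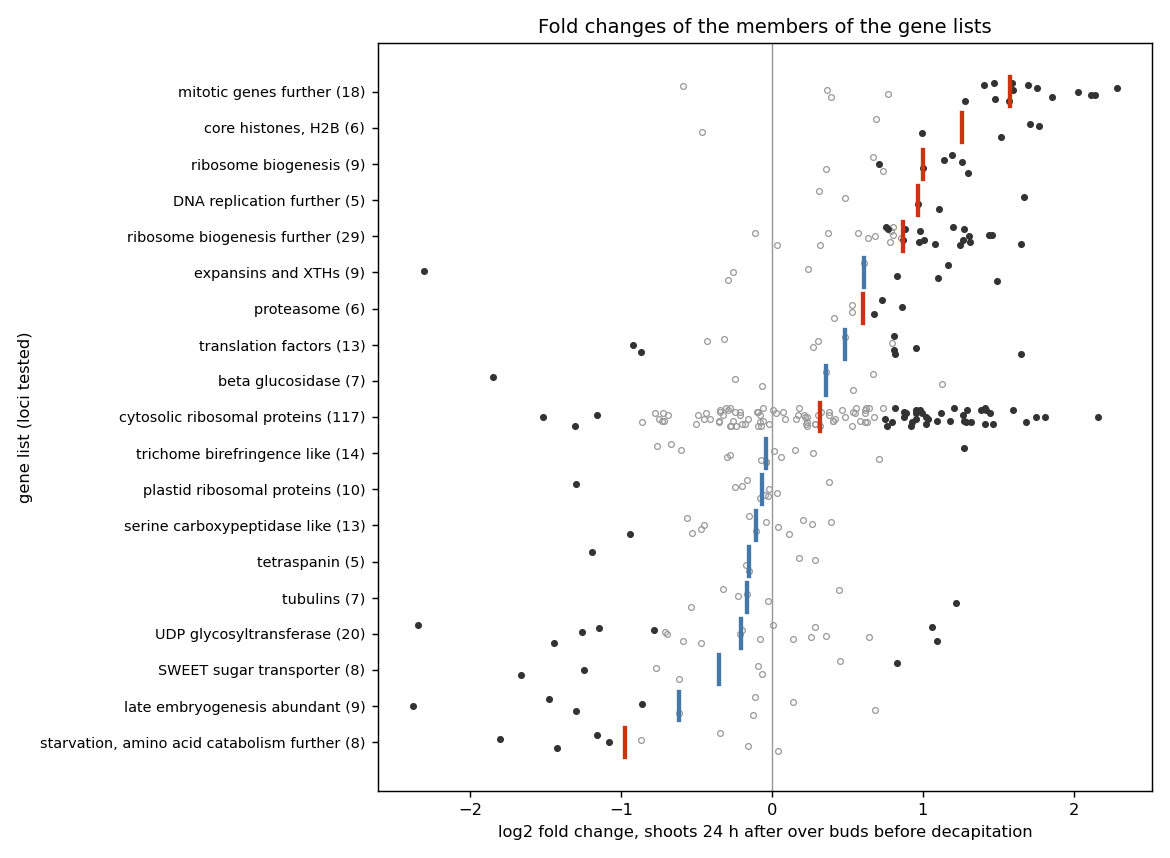
Log2 fold change of shoots over buds (horizontal axis) for each tested locus of 19 gene lists with at least 5 tested loci (vertical axis, number of loci in parentheses). Each point is 1 locus, filled where the adjusted p was 0.05 or less; the bar is the list median, red where the camera adjusted p was 0.05 or less and blue otherwise, and runs from −0.97 for the starvation list to 1.58 for the mitotic list.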

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

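The tests of scaling and of gene length for the gene lists, the test of scaling for shoot array 1 and both tests of bright ribosomal protein probe sets, with the bounds they were read against, were chosen after the result was seen. The tests of other splits and of brightness-matched probe sets were written before their values were computed.

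Mitotic, DNA replication and ribosome biogenesis lists were higher in shoots than in buds by camera with a preset correlation (adjusted p = 0.553 for each with an estimated correlation). The smallest median log2 fold change among the 4 lists under median, quantile or spike scaling was 0.88. Median and spike scaling add the same amount to every fold change. Here that amount was upward (median of all tested probe sets from −0.06 to 0.08 and 0.02), so neither could lower the lists. Quantile scaling could, and its smallest median was the 0.88, so scaling of that kind is not the whole cause. Fold changes were hardly related to gene length, introns included (Spearman's rho 0.027 over 7356 probe sets), and with that trend removed the smallest median was 0.85, so a length trend is not the whole cause either. Gene length is a weak stand-in for RNA quality, and of the 3' to 5' control ratios those of both actin sets (1.66 and 1.38 in buds against 0.990 and 1.14 in shoots for the newer) and an older GAPDH set differ with the group while those of GAPDH and ubiquitin overlap, so RNA quality stays open. Outgrowth itself and a changed share of dividing tissue are candidate explanations that were not tested.

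Of the ribosomal protein probe sets with a mean signal of 1000 or more, 0 of 26 passed the test. Both tests of this were fixed in part by that cut, since the highest signals of the arrays leave a mean of 1000 room only for log2 fold changes from −1.05 to 0.68. A ceiling of the signal is therefore neither supported nor excluded by medians that lay within 0.12 of the log2 ratios of the highest signals. A property of ribosomal protein genes alone is not decided either by other probe sets at 1000 or more, whose fold changes had an SD 0.279 times that of probe sets at 200 to 400. Both stay open, as do steadier expression of abundant transcripts and cross-hybridization between gene copies.

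Shoot array 1 lay further from the buds than shoot array 2: among probe sets called higher, 83.5% had the higher signal on shoot array 1 (median log2 difference 0.26), and among those called lower, 32.8% did. The difference in the probe sets called lower was −0.15, of opposite sign, which a scaling factor for the whole array does not give. A wider signal range of 1 array is argued against by uncalled probe sets of matched brightness, in which the gap between the 2 directions was −0.0188, compared with 0.41 in the called ones. Bud array 1 likewise lay further out, with medians of −0.10 and 0.10. Harvests at slightly different stages of outgrowth may underlie this, which the labels do not allow to be tested.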

How the results depend on the processing

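Scaling to spikes, leaving out bright probe sets and removing the length trend were chosen after seeing the data; the other alternatives were set before. No called probe set named here and no list that passed reversed under any of them. The cause of a changed call was not tested unless given.

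Counts of probe sets higher and lower (1388 and 1635) stayed within 1.5 times under other scalings, a pseudocount, other filters, no variance trend and without bright probe sets. A plain criterion of 2-fold in all 4 pairings gave 360 and 524. With each array left out in turn, where the lone array is assumed to vary like the other group, counts ranged from 230 to 1181 and from 432 to 1468, the lowest without shoot array 1 (655 of its 662 calls were also made with all 4 arrays). The replicate numbers give a replicate block: with it 2109 were higher and 2548 lower. Deviations from the group means correlated at 0.225 between arrays of the same number, but with 2 pairs this does not establish a pairing; the block changed no list call. Of the 3 splits of the 4 arrays into 2 and 2, 1 gave as many calls as the 3023 found, itself, and the highest of the others gave 0 (limma, with 116 and 13 at an unadjusted p under 0.05). The others mix bud and shoot arrays in each group, so the difference between buds and shoots widens their spread and holds their calls down. The contrast is therefore no support for the 3023 calls, and with 3 splits a share under 0.05 is out of reach.

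The 8 lists that passed missed the threshold with an estimated correlation (0.553 in each), and 7 did with fry (0.148 for cytosolic ribosomal proteins, histones, replication, mitosis and proteasome; 0.15 for both ribosome biogenesis lists). Few residual degrees of freedom make these misses hard to avoid. The medians of all 8 kept their direction with any 1 array left out. Without shoot array 1 they ran from −0.67 for starvation to 1.27 for mitosis. Camera's preset correlation of 0.01 treats loci as nearly independent, so its p-values depend little on the number of arrays. Estimated correlations of the 8 lists ran from −0.07 for starvation to 0.902 for the first ribosome biogenesis list. Late embryogenesis abundant genes passed with no filter (0.020), spike scaling (0.0246) and without bright probe sets (0.0447), and ranged from 0.0374 to 0.192 with 1 array left out; translation factors passed with no filter (0.0127), without bright probe sets (0.047) and with the length trend removed (0.0466); expansins and xyloglucan transglucosylases passed with the stricter filter (0.0112), where 16 lists could be tested. Of 107 genes followed, 46 calls were lost without shoot array 1, 15 without bud array 1, 10 with no filter and 9 without shoot array 2. The promoter motif test was not run. Noise in dim probe sets and the upper end of the scale limit what the signals resolve.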

Other observations

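The gene groups here were chosen after their values were seen and carry no test as a group; the actin 3' to 5' ratio (1.66 and 1.38 in buds, 0.990 and 1.14 in shoots) moved with all of them. Genes of anthocyanin and flavonoid synthesis were higher in the shoots: of 19 listed loci 9 had a named probe set, and all 8 tested loci rose, by 2.09-fold to 6.62-fold. DFR, dihydroflavonol reductase, rose 4.47-fold from 153 ± 2.01 to 684 ± 46.7, AT5MAT, an anthocyanin malonyltransferase gene, rose 5.85-fold, AT4G14090 5.42-fold, AT1G06000 3.59-fold, CHIL 3.38-fold and the flavonol glycosyltransferase genes UGT78D1 and UGT78D2 2.09-fold and 2.14-fold (n = 2 in each group, limma with Benjamini-Hochberg adjustment). Without shoot array 1, UGT78D1 missed the threshold (adjusted p = 0.0551).

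Of 8 tested ATG8 loci, whose products coat autophagosomes, 6 were lower in the shoots, with ATG8E 3.29-fold lower (148 ± 0.0387 to 45.5 ± 8.06) and ATG8F 2.51-fold lower (642 ± 21.0 to 259 ± 50.4); ATG8D and ATG8G, at −0.67 each on the log2 scale, did not pass. ATG8E alone passed without shoot array 1, 1 of 8, and 4 passed without shoot array 2. The gibberellin receptor genes GID1A (log2 fold change −1.13), GID1B (−1.85) and GID1C (−1.10) were all lower, with shoot signals at or below 23.1 for GID1B and GID1C that leave the sizes uncertain, and GID1C missed the threshold without shoot array 1 (adjusted p = 0.205), bud array 1 (0.205) or shoot array 2 (0.0760), with equal medians (0.0525), quantile normalization (0.0629) or no filter (0.0808).

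The largest fitted changes of all were in probe sets without a gene name here. In the largest decrease the signal was 1172 ± 80.0 in buds, in the range of 1000 or more where a ceiling was not excluded, and 37.2 ± 17.7 in shoots, a fitted 33.4-fold decrease whose size is uncertain. In the largest increase it was 13.1 ± 6.20 in buds, not shown to be above background, and 177 ± 24.2 in shoots, 14.2-fold higher, or 9.57-fold with a pseudocount of 6.41 (n = 2 in each group).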
